A study of Drosophila melanogaster with 8 samples.

How the data were processed

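Genomic DNA from dissected midguts with their tracheal cells was digested with DpnI, ligated to DamID adaptors, cut with DpnII and amplified, and libraries were made with the NEBNext Ultra II kit, per the labels' protocols. Flies were crossed at 18 °C, and their progeny were collected every 48 hours, aged for 7 days and moved to 29 °C for 24 hours before dissection. There were 8 libraries, Dam and Dam-Pol II in 2 replicates of each condition, and 4 deposited profiles, each assigned to the Dam-Pol II sample of its condition and replicate. The deposited values are log2 ratios of Dam-Pol II over Dam per GATC fragment, as read from their range and their values below 0, since the log base, the aligner, the scaling and the step that made the ratio are not given in the sources used here. Per the submitters' processing notes the genome build is BDGP 6. The profile of Suc replicate 2 carries the track number 3 in its file, and its replicate number was taken from the labels. Depth is unknown, and no interval or floor that needs it was computed. The labels call the replicates biological.

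Gene coordinates came from a RefSeq gene table of Release 6, matched by chromosome and position. The 28 mitochondrial fragments were left out, because their coordinates run to 21384, and 383654 nuclear fragments remained, with a median length of 197 bp. A gene's value in a profile is the mean log2 ratio of the fragments that overlap it from start to end, weighted by overlap length. Of 15930 protein coding and lncRNA genes, 14089 had at least 3 fragments, 96 listed at 0 in every profile were left out, and 13993 were tested, 13047 protein coding and 946 lncRNA, with a median of 11 fragments. At 75.0% of them a fragment was shared with another gene. The table used here gives no exons or strand, so overlapping genes cannot be told apart, and near-identical trypsin genes may share reads.

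Genes were tested with limma 3.58.1 in R 4.3.3, with 1 spread shared by both conditions and a prior variance trended on the number of fragments. Pe was compared with Suc two-sided, and each group mean with 0 one-sided, with Benjamini-Hochberg adjustment at 0.05. The 33 gene lists, fixed before the data were examined, were tested with limma's camera at a preset inter-gene correlation of 0.01, against all other genes, when at least 3 members were tested. Camera with an estimated correlation and limma's fry were alternatives. Genes named in the text follow a rule fixed at the same time. It takes the 12 largest differences per direction among called genes whose groups did not overlap, filled up with the smallest unadjusted p, the 10 highest occupied genes per condition, a fixed set of tracheal, hypoxia, stress and cell type genes, and up to 4 members per list with the smallest p.

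The fits were tested on simulated profiles with the fitted spread, in which 200 of 13993 genes were changed. The mean estimate was 0.99 for genes changed by 1 and 2.03 for genes changed by 2, and 3 unchanged genes were called. Of 33 random lists of 20 genes, camera called the 3 lists shifted by -0.5 and 0 others. Genes were simulated independently of each other, while the estimated inter-gene correlation in the data was, for example, 0.262 in the tracheal list. The simulation therefore does not show how often camera calls unshifted lists of correlated genes. The alternatives were other scalings of the profiles, other filters on fragment number and length, other gene values, fragments of a single gene, 1 prior variance, the replicate number as a block, leaving out each profile, a difference of 1 without a test and random placement of 10000 runs of fragments. Gene values and tests of explanations were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Random lists were drawn 10000 times, matched in 50 bins on mean occupancy or fragment number.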

Results

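RNA polymerase II (Pol II) occupancy was profiled by targeted DamID in terminal tracheal cells, the branched air-supplying cells that lie on the adult Drosophila midgut. A bacterial DNA adenine methyltransferase (Dam), free or fused to Pol II, was expressed from a Dam construct under dSRF-GAL4, and DNA methylated at GATC sites was sequenced. Flies were fed sucrose (Suc) or sucrose with a bacteria solution labelled Pe, which the labels equate with a damaged intestine, for the last 16 hours of a 24 hour induction. The 8 samples form 4 groups of 2, Dam and Dam-Pol II in each condition, and 60 midguts were dissected for each condition and replicate. Each pair of Dam-Pol II and Dam libraries is represented by 1 profile, so that 2 Pe and 2 Suc profiles were compared. Each profile gives a value for 383654 GATC fragments of the nuclear chromosomes, read here as a log2 ratio of Dam-Pol II over Dam. Sequencing depth is unknown, because the profiles hold no counts, and precision rests on 2 profiles per condition.

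The first comparison asks which genes carried Pol II signal under homeostasis and under damage. Among genes called occupied, the uncharacterised gene CG12310 had the highest mean log2 ratio in both conditions, 4.08 ± 0.73 in Suc and 4.23 ± 1.14 in Pe (SD, n = 2). Among the 10 highest such genes of both conditions were COX5B, a subunit of cytochrome c oxidase, at 3.63 ± 0.23 in Suc and 3.18 ± 0.19 in Pe, and Cog7, a subunit of a Golgi tethering complex, at 3.76 ± 0.65 and 3.09 ± 0.57. The histone gene His4r, a replication-independent H4 copy, reached 3.47 ± 0.73 and 3.46 ± 0.59. Hoip, a component of the spliceosomal small ribonucleoprotein, was among the 10 highest in Suc (hoip, 3.65 ± 0.91), and NLaz, a secreted lipocalin, among those in Pe (3.05 ± 0.51).

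In the one-sided limma test of the group mean against 0, 2982 of 13993 genes were occupied in Suc and 1056 in Pe at a Benjamini-Hochberg adjusted p under 0.05, and 1023 genes were called in both. These 2 counts were not tested against each other. The Pe count was 0 without Pe replicate 1 or without Pe replicate 2, and 3306 without either Suc replicate. The Suc count was 0 without either Pe replicate, 862 without Suc replicate 2 and 3940 without Suc replicate 1. After quantile normalization 4373 genes were called in Pe and 4369 in Suc, and under median and MAD scaling 3091 and 1868. Which condition had more occupied genes therefore depended on the scaling.

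Of 17 genes of tracheal identity and terminal branching, 6 were called occupied in Suc and 1 in Pe. The gene bs, which encodes the serum response factor whose enhancer drives the GAL4 line, had a mean of 0.99 ± 0.20 and an adjusted limma p of 0.0234. The FGF receptor gene btl had a mean of 0.97 ± 0.11 and an adjusted limma p of 0.0268, and stumps, its downstream adaptor, had 1.30 ± 0.35 and 0.0229. The early tracheal regulator trh lay at 0.37 ± 0.06 with an adjusted limma p of 0.175. The gene puc, a JNK phosphatase and pathway target, stood at 1.96 ± 0.86 in Suc. Polr2A, which encodes the largest Pol II subunit, stood at 2.23 ± 0.40 in Suc and 2.03 ± 0.50 in Pe, and targeted DamID commonly fuses Dam to a Pol II subunit, so reads from the transgene can add to a subunit gene.

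Housekeeping groups stood above other genes in both conditions in camera with a preset correlation of 0.01. No list call, here or for the other groups, held with an estimated correlation (smallest adjusted p = 0.708 in Suc and 0.778 in Pe with an estimated correlation). That alternative rests on only 2 residual degrees of freedom, so it had little power to call any list. For guidance cues and receptors in Suc its estimated correlation, 0.0190, was near the preset 0.01. The camera p of that list still rose from 0.00792 to 0.132. The loss of calls therefore does not show that correlation between genes removed them. The 82 genes of cytosolic ribosomal proteins had a mean 0.97 above other genes in Suc and 0.85 in Pe, the 15 glycolysis and sugar transport genes 0.98 and 0.75, and the 22 oxidative phosphorylation genes 0.63 and 0.57. The components of the Imd and Toll pathways, which sense bacteria, stood 0.54 above other genes in Suc and 0.42 in Pe. Oxidative stress genes stood 0.60 and 0.41 above, the unfolded protein and integrated stress response 0.85 and 0.71, heat shock proteins 0.42 and 0.41, actin, tubulin and adhesion genes 0.47 and 0.35, autophagy 0.48 and 0.40, apoptosis 0.40 and 0.33, and lipid storage and metabolism 0.42 and 0.33. The hypoxia response stood 0.67 above other genes in Suc (camera adjusted p = 0.0632) and 0.46 in Pe, where it was called, insulin and TOR signalling was called in Suc (0.23 above) and stood 0.16 above in Pe, and the difference between conditions was not called for either. With the preset correlation 15 of 33 lists differed from other genes in Suc, 13 above and 2 below, and 13 lists stood above other genes in Pe. Without Pe replicate 1 the Pe calls of the hypoxia (0.39), oxidative stress (0.29), actin (0.33) and autophagy (0.45) lists were lost. Without Pe replicate 1 and without Pe replicate 2 the Pe calls were lost for apoptosis (0.35 and 0.31), the unfolded protein response (0.76 and 0.66) and lipid storage (0.34 and 0.33). The apoptosis call in Suc was lost without either Pe replicate (0.40). The insulin and TOR call was lost without Suc replicate 2 (0.17, camera adjusted p = 0.154) and without either Pe replicate (0.23, camera adjusted p = 0.0762).

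Markers of several cell types that a dissected midgut holds were compared in the same way. The 24 enterocyte markers, mostly digestive enzymes of the absorptive gut epithelium, stood 0.66 above other genes in Suc (camera adjusted p = 0.00203) and 0.27 above in Pe (camera adjusted p = 0.0254; adjusted p = 0.708 and 0.778 with an estimated correlation). The value in Pe was 0.0756 without Pe replicate 1 (camera adjusted p = 0.409) and 0.47 without Pe replicate 2, and the Pe call was also lost without either Suc replicate (0.27 as before, camera adjusted p = 0.0666), after quantile normalization (0.33, camera adjusted p = 0.138) and with 10 or more fragments per gene (0.15, camera adjusted p = 0.220). With 10 or more fragments the Suc call was lost too (0.51, camera adjusted p = 0.0972). The 17 genes of tracheal identity and terminal branching stood 0.21 above other genes in Suc (camera adjusted p = 0.0653) and 0.04 below, at -0.04, in Pe. In Suc this list was called with no filter on fragment number (0.23, camera adjusted p = 0.0488) and with unweighted means (0.21, camera adjusted p = 0.0454). Neuron markers (-0.35) and guidance cues and receptors (-0.28) lay below other genes in Suc, and both calls were lost with an estimated correlation (adjusted p = 0.708 with an estimated correlation) and without Suc replicate 2 (-0.22 and -0.19, camera adjusted p = 0.154 and 0.136). Markers of intestinal stem cells and enteroblasts (-0.08), enteroendocrine cells (-0.25), muscle (0.01), haemocytes (-0.28) and fat body (-0.14) were not called in Suc, nor in Pe, where they stood at -0.23, -0.24, -0.07, -0.25 and -0.29. The airway chitin and luminal matrix list stood at 0.06 in Suc and -0.02 in Pe. Mhc, the muscle myosin heavy chain, lay at 0.01 ± 0.06 in Suc, pros, an enteroendocrine regulator, at -0.05 ± 0.02, and Hml, a haemocyte gene, at -0.05 ± 0.01.

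**Figure D1:**
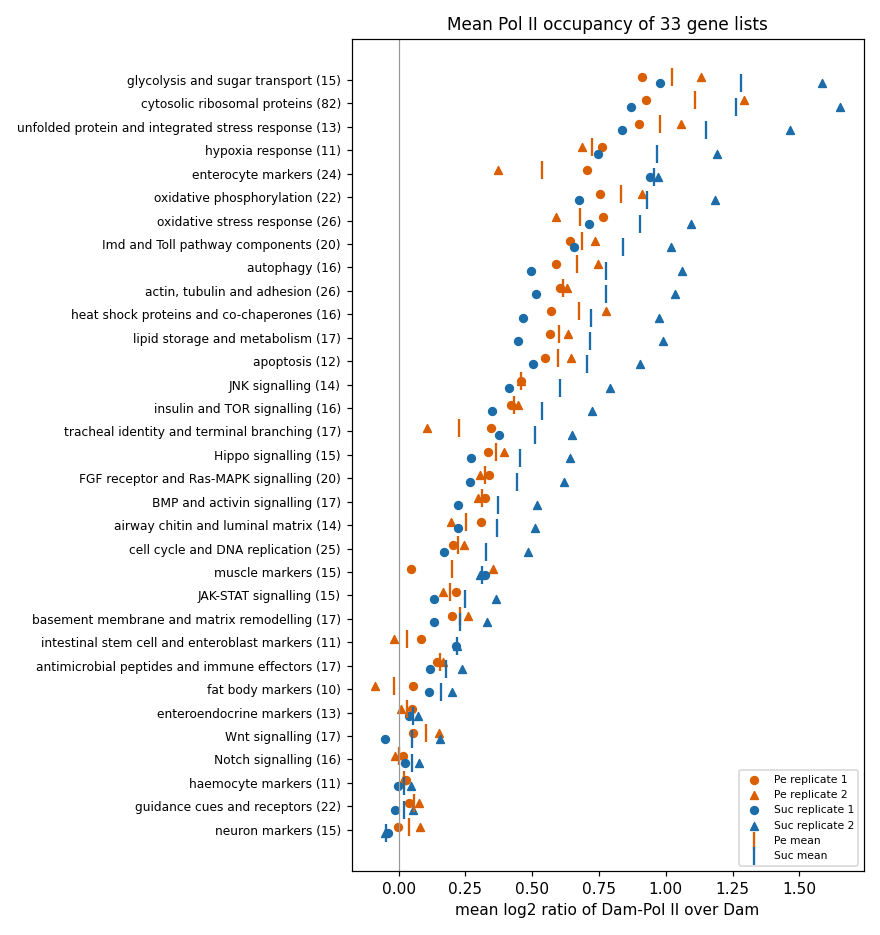
Mean log2 ratio of Dam-Pol II over Dam (horizontal axis) of each of 33 gene lists, with the number of tested genes in brackets, in each Pe (orange) and Suc (blue) profile, circles for replicate 1, triangles for replicate 2 and bars for the mean of both. Both Pe profiles lie below both Suc profiles for enterocyte markers (0.70 and 0.37 against 0.94 and 0.97) and for the tracheal list (0.35 and 0.11 against 0.38 and 0.65).

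The second comparison asks how Pol II occupancy in these cells differed between bacteria-fed and sucrose-fed flies. The lists of enterocyte markers and of tracheal identity and terminal branching were lower in Pe than in Suc. The enterocyte list lay 0.38 below other genes, at -0.38 (camera adjusted p = 0.00128; adjusted p = 0.935 with an estimated correlation), and 18 of its 24 genes had a negative difference. The neighbouring and similar trypsin genes, between which reads can be shared, are uncertain: alphaTry and epsilonTry had differences of -1.58 (SE 0.23) and -1.15 (SE 0.11), betaTry -1.47 (SE 0.43; -1.97 without Pe replicate 1 and -0.98 without Pe replicate 2), and Amy-p, an amylase, -0.69 (SE 0.14). No enterocyte marker passed over all genes, and 1, epsilonTry, passed when adjusted over the list alone (limma adjusted p = 0.0299).

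The tracheal list lay 0.25 below other genes, at -0.25 (camera adjusted p = 0.0359; adjusted p = 0.935 with an estimated correlation), and 13 of its 17 genes had a negative difference. The value was -1.60 (SE 0.51) at kni, a nuclear receptor gene that patterns tracheal branches, -0.58 (SE 0.16) at bs, -0.64 (SE 0.21) at btl and -0.36 (SE 0.11) at Cad99C, a cadherin gene. Leaving out 1 profile at a time gave -2.23 to -0.96 at kni, -0.73 to -0.44 at bs, -0.88 to -0.39 at btl and -0.46 to -0.27 at Cad99C, in each case from without Pe replicate 1 to without Pe replicate 2. For kni the 2 Pe profiles stood at 0.69 and -0.59, and the 2 Suc profiles at 1.51 and 1.79. No gene of the list passed over all genes, and 0 passed when adjusted over the list alone. Both list calls were lost without Pe replicate 2 (-0.19 and -0.10, camera adjusted p = 0.154 and 0.161), without Suc replicate 1 (-0.27 and -0.26, camera adjusted p = 0.115 for both), after quantile normalization (-0.29 and -0.21, camera adjusted p = 0.236 and 0.265) and under median and MAD scaling (-0.22 and -0.23, camera adjusted p = 0.0652 and 0.0996). The tracheal call was also lost without Suc replicate 2 (-0.24, camera adjusted p = 0.0665), with the median of the fragments (-0.18, camera adjusted p = 0.0907) and with fragments of 1 gene (-0.24, camera adjusted p = 0.0637). Over all alternatives camera's adjusted p ranged from 6.73e-06 to 0.935 for the enterocyte list and from 0.000431 to 0.935 for the tracheal list.

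**Figure D2:**
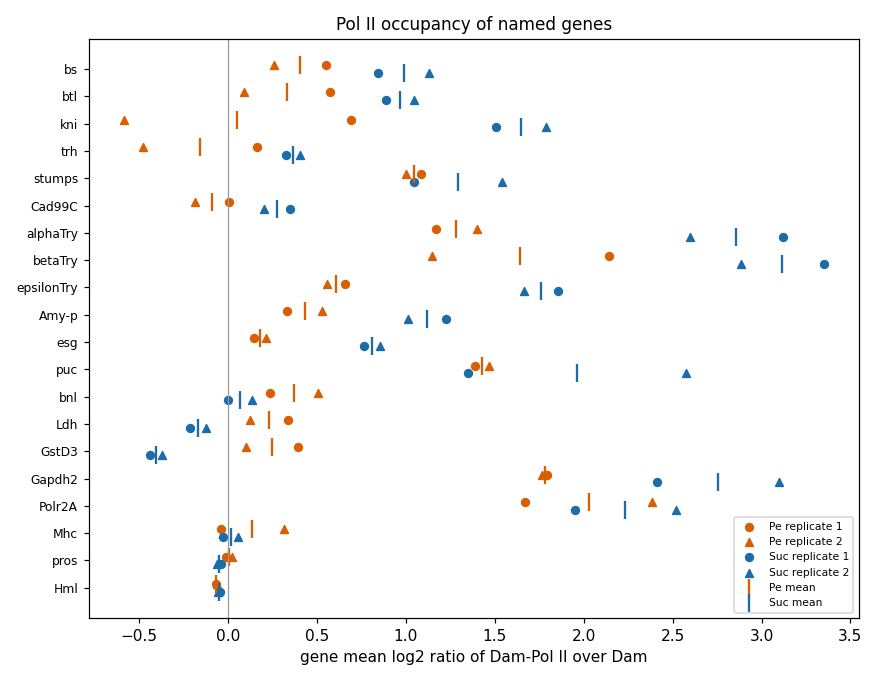
Gene mean log2 ratio of Dam-Pol II over Dam (horizontal axis) of 20 named genes in each Pe (orange) and Suc (blue) profile, circles for replicate 1, triangles for replicate 2 and bars for the mean of both. At alphaTry both Pe profiles (1.17 and 1.40) lie below both Suc profiles (3.12 and 2.60), and at Ldh both Pe profiles (0.34 and 0.13) lie above both Suc profiles (-0.21 and -0.13).

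**Figure D3:**
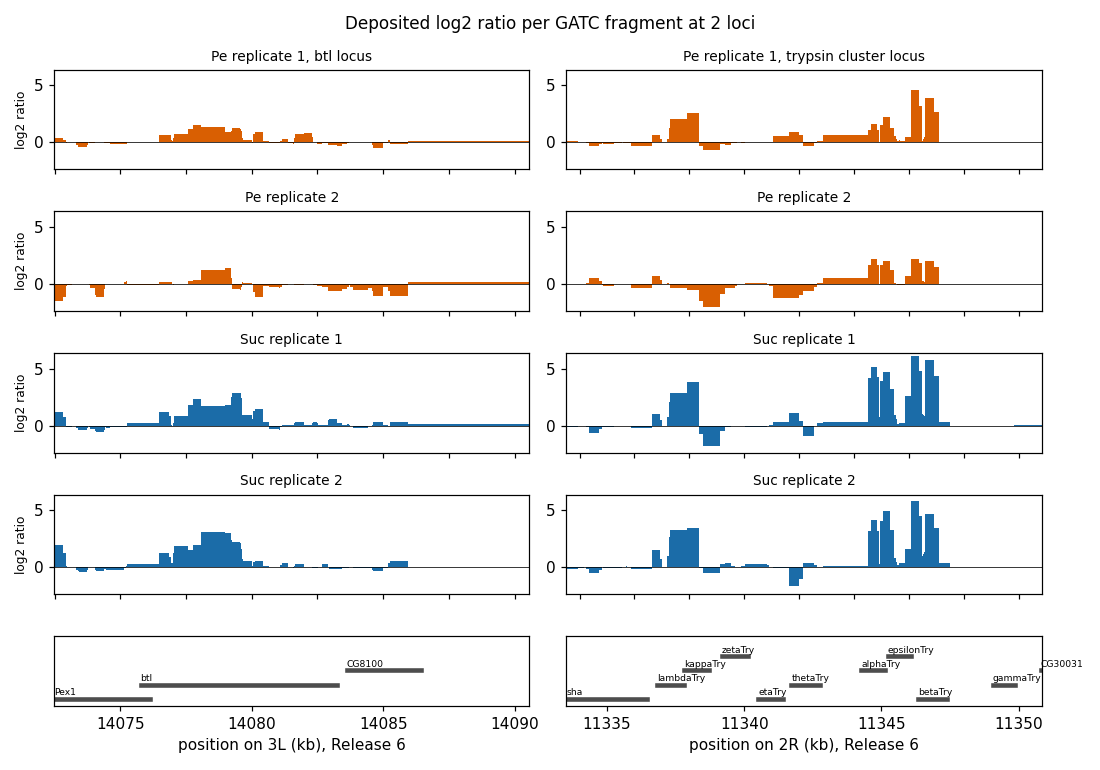
Deposited log2 ratio per GATC fragment (vertical axis) against position in kb at btl on 3L and at part of a cluster of trypsin genes on 2R, in each Pe (orange) and Suc (blue) profile, with tested genes drawn as grey bars below. The gene mean of btl is 0.57 and 0.09 in the Pe profiles and 0.89 and 1.05 in the Suc profiles.

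No single gene differed between the conditions. In the two-sided limma test 0 of 13993 genes were higher and 0 were lower in Pe (smallest adjusted p = 0.897), and 549 had an unadjusted p under 0.05, 231 of them higher and 318 lower. That split turned to 379 higher and 322 lower after quantile normalization, 221 and 104 under median and MAD scaling and 305 and 147 without Suc replicate 2, and was 32 and 1573 without Suc replicate 1. No fit with another setting called a gene. Both Pe profiles lay above both Suc profiles at 3218 genes and below at 1959, together 37.0% where chance gives 33.3%. The split by replicate number separated 40.3% of genes, more than the split by condition, and the remaining split 22.6%. A difference of at least 1 with no overlap was seen at 9 genes higher and 112 lower in Pe. The 95th percentile of gene values was 1.24 and 1.48 in the Pe profiles and 1.33 and 2.06 in the Suc profiles. No count expected from these ranges was computed, so the counts do not show a lowering by Pe. On simulated profiles of this comparison with 13993 genes, the test recovered 22 of 100 genes changed by 1 and 80 of 100 changed by 2 on the log2 scale. Genes in these simulated profiles were drawn independently of each other.

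The genes with the smallest unadjusted p are given as values, since none passed. With a lower mean in Pe these were CG15263 (-1.35, SE 0.10), CG13067 (-1.18, SE 0.11), epsilonTry, CG17359 (-0.84), Rrp42 of the RNA exosome (-0.87), Vha14-1 of the vacuolar proton pump (-0.71), the syntaxin gene Syx8 (-0.87), CG3091 (-0.96), esg, CG14687 (-0.72), CG32563 (-0.58) and Cndp2 (-0.93). The gene esg, a transcription factor of intestinal stem cells and enteroblasts that also acts in tracheal development, had a mean of 0.18 ± 0.05 in Pe and 0.81 ± 0.06 in Suc, and passed when adjusted over its list alone (limma adjusted p = 0.0452). With a higher mean in Pe these were CG15563 (1.20, SE 0.09), CG32115 (0.70), CG42591 (0.66), Pig1 (0.76), the seminal fluid gene Acp36DE (0.48), lncRNA:CR43606 (0.57), CG13689 (0.45), the adhesion gene Fas3 (0.37), CG42713 (0.48) and lncRNA:CR44042 (0.56). The values of CG15563, CG32115, CG42591, Acp36DE, CG42713 and lncRNA:CR44042 lay below 0 in both conditions, so that their difference is between negative ratios (-0.24 in Pe and -1.44 in Suc at CG15563), and so did those of CG32563. The genes rg and CG15465 share their coordinates and their value (0.23), and many of the short genes named here rest on 3 to 12 fragments, some shared with a neighbour.

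Oxygen, stress and immune genes were examined because of the treatment. In the hypoxia list (-0.21 relative to other genes, not called), Ldh, lactate dehydrogenase, had a mean of 0.23 ± 0.15 in Pe and -0.17 ± 0.06 in Suc, and Gapdh2, a glycolytic enzyme, 1.78 ± 0.02 and 2.75 ± 0.49. The FGF ligand gene bnl had a difference of 0.30 (SE 0.12), the hypoxia factor gene sima -0.09 (SE 0.10) and its prolyl hydroxylase gene Hph -0.28 (SE 0.19). Leaving out 1 profile gave 0.17 to 0.44 at bnl, -0.44 to -0.12 at Hph and -1.32 to -0.63 at Gapdh2. In the oxidative stress list (-0.19, camera adjusted p = 0.0527; -0.31 without Pe replicate 1, where it was called, and -0.0750 without Pe replicate 2), GstD3, a glutathione transferase gene, had a difference of 0.65 (SE 0.14) and Trx2, a thioredoxin gene, -1.12 (SE 0.26). The regulators cnc and Keap1 had differences of 0.06 (SE 0.10) and -0.20 (SE 0.30). The JNK target puc had -0.53 (SE 0.48), the JAK-STAT target Socs36E 0.03 (SE 0.24), the matrix protease gene Mmp1 -0.48 (SE 0.24; -0.71 without Pe replicate 1 and -0.26 without Pe replicate 2), and PGRP-SC2, an amidase that degrades peptidoglycan, 0.34 (SE 0.08). The Notch target E(spl)mbeta-HLH had -1.26 (SE 0.30). Differences at stumps, trh, Polr2A and w were -0.25, -0.52, -0.21 and 0.16, and leaving out 1 profile gave -0.50 to -0.00479 at stumps, -0.85 to -0.20 at trh and 0.0223 to 0.30 at w. The differences at puc, sima, stumps and Polr2A turn positive under median and MAD scaling, and that at Polr2A also under quantile normalization. None of these genes passed, and 0 passed when adjusted over its list alone.

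The other lists were not called between the conditions in the main fit. With all 4 profiles but no filter on fragment number, 3 were called. These were oxidative stress (-0.20, camera adjusted p = 0.0294), Imd and Toll components (-0.13, 0.0373) and ribosomal proteins (-0.12, 0.0459). Unweighted means called oxidative stress (-0.18) and Imd and Toll components (-0.10), and the median of the fragments called ribosomal proteins (-0.16). Oxidative stress was also called with the stricter filter on fragment number (-0.25). Without Suc replicate 1, 11 lists were called, among them ribosomal proteins (-0.38), lipid storage, actin, neurons, glycolysis, oxidative phosphorylation, autophagy, Imd and Toll components, guidance and Hippo signalling, and without Pe replicate 2 muscle markers, ribosomal proteins and Imd and Toll components were called. Relative to other genes, the differences were -0.23 for glycolysis and sugar transport, -0.12 for Imd and Toll pathway components, 0.01 for antimicrobial peptides and immune effectors, -0.02 for JAK-STAT, -0.11 for JNK, -0.01 for heat shock proteins and co-chaperones, -0.14 for the unfolded protein and integrated stress response, -0.07 for insulin and TOR, 0.09 for Wnt, -0.01 for Notch, -0.02 for BMP and activin, and -0.06 for Hippo signalling. They were 0.07 for guidance cues and receptors, -0.12 for actin, tubulin and adhesion, 0.03 for basement membrane and matrix remodelling, -0.07 for cell cycle and DNA replication, -0.07 for apoptosis, -0.06 for oxidative phosphorylation, -0.12 for cytosolic ribosomal proteins, -0.08 for lipid storage and metabolism, -0.07 for autophagy, -0.08 for airway chitin and luminal matrix, and -0.09 for FGF receptor and Ras-MAPK signalling. Among cell type markers they were -0.15 for intestinal stem cells and enteroblasts, 0.01 for enteroendocrine cells, -0.08 for muscle, 0.03 for haemocytes, -0.14 for fat body and 0.12 for neurons. Under median and MAD scaling the differences turned positive for glycolysis, Imd and Toll components, heat shock, unfolded protein response, actin, apoptosis, oxidative phosphorylation, ribosomal protein, lipid and autophagy lists, and negative for antimicrobial peptide, guidance, enteroendocrine and haemocyte lists. Under quantile normalization the same held for the heat shock, unfolded protein response, apoptosis, oxidative phosphorylation, ribosomal protein, lipid, autophagy, antimicrobial peptide, enteroendocrine and haemocyte lists. The mean, median and test differed in sign for antimicrobial peptides, basement membrane and haemocyte lists.

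The profiles were also compared with each other across genes, which are not independent replicates. Pe replicate 1 correlated more with the Suc profiles (Pearson r = 0.918 and 0.926) than with Pe replicate 2 (0.833). The Suc profiles correlated at 0.901, and Pe replicate 2 correlated with them at 0.745 and 0.829. Fragments listed at exactly 0 made up 26% of Pe replicate 2 and 16.7%, 15.2% and 15.8% of Pe replicate 1, Suc replicate 1 and Suc replicate 2. The SD across genes was 0.48 and 0.58 in the Pe profiles and 0.55 and 0.77 in the Suc profiles.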

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

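The alternatives that leave out fragments listed at 0 were chosen after seeing the data. The counts of 0 genes higher and 0 lower in Pe held in all 18 fits, and the smallest adjusted p over them was 0.370, without Suc replicate 1. A difference of 1 with no overlap, for which no expected count was computed, gave 9 higher and 112 lower. The enterocyte list kept its negative direction under 19 of 19 alternatives and its call under 13 (-0.58 to -0.19, camera adjusted p from 6.73e-06 to 0.935), and the tracheal list its direction under 19 and its call under 9 (-0.40 to -0.10, camera adjusted p from 0.000431 to 0.935). Fry, which tests a list against no change and not against other genes, gave an adjusted p of 0.953 for both. The replicate block, 1 prior variance, the estimated correlation and fry reuse the list difference of the main fit, so their direction was fixed. Camera was run on the gene values and not on the variances of the gene test. Its calls with 1 prior variance were therefore fixed too. The exon-only and transcript-start alternatives were not run, because the gene table used here lists neither. Random placement compared genes with 10000 random runs of fragments at a threshold of 0.01, and not their means with 0 at 0.05. The number of runs also bounds its smallest p. Its counts of 0 occupied genes therefore answer a different and stricter question. They cannot decide whether the genes called in Suc and Pe were occupied. Depth is unknown, so what it limits cannot be stated. In leave-one-out fits the lone profile of a condition is assumed to vary like the others. Leaving out a Pe profile leaves the Suc means unchanged. The Suc count then changes only through the shared spread, which rests on the Suc profiles alone. Likewise, leaving out a Suc profile leaves the Pe means unchanged, and the shared spread then rests on the Pe profiles alone. Leaving out either Suc profile therefore gives the same Pe calls, so these fits are not separate checks of Pe. The same holds for the Suc calls and the Pe profiles. The causes of the other shifts given here were not tested.

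Lists called between conditions numbered 2, and 0 under quantile normalization, 0 under median and MAD scaling, 5 with no filter, 4 with unweighted means, 1 with fragments of 1 gene, 0 with an estimated correlation and 0 with fry, and from 1 to 11 over the leave-one-out fits. Genes occupied in Suc, 2982, numbered 1868 under median and MAD scaling, 1640 with 10 or more fragments, 1010 with the median of the fragments, 0 by random placement, and from 0 to 3940 over the leave-one-out fits. Genes occupied in Pe, 1056, numbered 4373 under quantile normalization, 3091 under median and MAD scaling, 293 with 10 or more fragments, 0 with the median of the fragments, 94 with fragments of 1 gene, 2017 without fragments at 0 in any profile, 0 by random placement, and from 0 to 3306 over the leave-one-out fits. Lists called in Pe numbered 8 with 10 or more fragments, 0 with an estimated correlation and from 6 to 12 over the leave-one-out fits, and lists called in Suc 0 with an estimated correlation and from 12 to 16 over the leave-one-out fits.

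The samples share only a number, since the labels name no shared animals, batch or day. The deviations of same-numbered profiles correlated at 0.285, and 2 pairs are too few to decide from this whether the numbers mark a shared origin. With the replicate block, 0 genes were higher and 0 lower in Pe, 3291 genes were occupied in Pe and 4012 in Suc, and 1 list, the enterocyte markers, was called between conditions, with an adjusted p of 0.0834 for the tracheal list. The calls above other genes in Pe were lost for enterocyte markers (camera adjusted p = 0.0658), hypoxia (camera adjusted p = 0.0658) and lipid (camera adjusted p = 0.0588). In Suc the insulin and TOR call was lost (camera adjusted p = 0.105). Lists called against other genes numbered 14 in Suc and 10 in Pe. Genes at an unadjusted p under 0.05 numbered 457 higher and 364 lower.

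Differences between Pe and Suc, and list values against other genes where named so, turned in sign as follows. Under quantile normalization of the gene means the values were antimicrobial peptides -0.0217, heat shock 0.0835, unfolded protein response 0.0378, apoptosis 0.00873, oxidative phosphorylation 0.0683, ribosomal proteins 0.0954, lipid 0.0146, autophagy 0.0442, enteroendocrine markers -0.0593, haemocyte markers -0.0379 and Polr2A 0.16. Under median and MAD scaling of each profile the values were glycolysis 0.0777, antimicrobial peptides -0.0284, Imd and Toll 0.0536, heat shock 0.13, unfolded protein response 0.14, guidance -0.0114, actin 0.018, apoptosis 0.0539, oxidative phosphorylation 0.15, ribosomal proteins 0.20, lipid 0.046, autophagy 0.0788, enteroendocrine markers -0.0744, haemocyte markers -0.0571, stumps 0.15, sima 0.0562, puc 0.0400 and Polr2A 0.55. With no filter on fragment number the values were antimicrobial peptides -0.0268 and haemocyte markers -0.0195. With genes of 10 or more fragments the values were antimicrobial peptides -0.38, ribosomal proteins 0.0732 and airway chitin in Pe against other genes 0.00898. With the unweighted mean of the fragments the values were Notch signalling 0.0145, cnc -0.0216 and Socs36E -0.0367. With the median of the fragments the values were Notch signalling 0.0444, BMP and activin signalling 0.029, Socs36E -0.0146, w -0.0414 and Hml 0.0158. With fragments of 1 gene only the values were antimicrobial peptides -0.0208, BMP and activin signalling 0.00445 and airway chitin in Pe against other genes 0.0144. With fragments of 100 to 2000 bp the value was antimicrobial peptides -0.0365. Without fragments listed at 0 in any profile it was antimicrobial peptides -0.00926.

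Leaving out 1 profile at a time gave Keap1 -0.55 to 0.14, Mhc -0.0568 to 0.30, Polr2A -0.56 to 0.15, Socs36E -0.18 to 0.25 and cnc -0.0609 to 0.19. Further ranges were puc -1.15 to 0.0774, sima -0.20 to 0.0211, BMP and activin signalling -0.0676 to 0.0186, Hippo signalling -0.12 to 0.00136 and JAK-STAT signalling -0.0763 to 0.0322. It also gave Notch signalling -0.12 to 0.0875, actin -0.26 to 0.00926, airway chitin -0.17 to 0.00509, antimicrobial peptides -0.054 to 0.0788 and autophagy -0.23 to 0.0819. Ranges were also ribosomal proteins -0.38 to 0.15, enteroendocrine markers -0.0998 to 0.12, guidance -0.0194 to 0.17, haemocyte markers -0.0692 to 0.14 and heat shock -0.14 to 0.12. Other ranges were lipid -0.23 to 0.0622, muscle markers -0.21 to 0.0596, neuron markers -0.0125 to 0.25, oxidative phosphorylation -0.19 to 0.0656 and unfolded protein response -0.33 to 0.0516. It also gave airway chitin in Pe against other genes -0.10 to 0.0698, muscle markers in Pe against other genes -0.19 to 0.0576, tracheal identity in Pe against other genes -0.19 to 0.11, intestinal stem cell markers in Suc against other genes -0.21 to 0.0406 and muscle markers in Suc against other genes -0.13 to 0.15.

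Among differences that kept their sign, leaving out 1 profile moved by over 1.5 times glycolysis -0.40 to -0.0480, hypoxia -0.31 to -0.11, oxidative stress -0.31 to -0.0750, Imd and Toll -0.17 to -0.0610, JNK -0.17 to -0.0487 and insulin and TOR -0.13 to -0.00953. It moved likewise FGF receptor and Ras-MAPK -0.14 to -0.0402, apoptosis -0.15 to -0.00217, basement membrane 0.00440 to 0.0603, cell cycle -0.0998 to -0.0395, fat body -0.24 to -0.0406 and stem cell and enteroblast -0.28 to -0.0254. Against other genes it moved fat body markers in Pe -0.39 to -0.18, stem cell markers in Pe -0.32 to -0.15, enteroendocrine markers in Suc -0.36 to -0.14, fat body markers in Suc -0.23 to -0.0593, haemocyte markers in Suc -0.38 to -0.18, neuron markers in Suc -0.48 to -0.22 and lipid in Suc 0.27 to 0.56. Between conditions, oxidative stress was called under 6 alternatives, Imd and Toll under 4 and ribosomal proteins under 4. Calls against other genes lost with 10 or more fragments were unfolded protein response and enterocyte markers in both conditions, insulin and TOR and autophagy in Suc, and hypoxia, oxidative stress and actin in Pe. With the median of the fragments they were actin and lipid in both, unfolded protein response and insulin and TOR in Suc, and hypoxia and oxidative stress in Pe.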

Other observations

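The tests of sampling noise, of signal from gut epithelial cells and of the added checks were chosen only after the result was seen, and the salivary gland test after genes high in Pe replicate 2 had been inspected.

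A list of 11 salivary gland and secretory genes was written after genes high in Pe replicate 2 had been inspected, which prompted the idea, but before the values of the listed genes were seen. The gene fkh, a forkhead factor of the salivary gland that is also expressed in gut, had gene values of 1.64 and 2.65 in the Pe profiles and 2.01 and 2.59 in the Suc profiles. The salivary gland factor gene sage had 1.03 and 1.64 in Pe and 1.18 and 1.76 in Suc, and CrebA, a regulator of secretory capacity, had means of 1.72 in Pe and 1.86 in Suc, while the gland genes PH4alphaSG1 and PH4alphaSG2 had -0.18, -0.15, -0.40, -0.31 (Pe, then Suc) and 0.25, 0.32, 0.28, 0.32. The list mean was 0.83 in Suc and 0.86 in Pe, at the 99.8th and 99.99th percentiles of random lists matched on the number of fragments. CrebA, Papss, sll and Tango1 act in secretion in many tissues, and fkh in gut.

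Pe replicate 2 stands apart from the other 3 profiles. Against sampling noise as the whole cause, the gap between its mean correlation with the others and the mean correlation among the others was -0.1245 in the 1037 genes with at least 60 fragments (95% bootstrap interval -0.166 to -0.0917), and -0.113 in all genes. A candidate explanation is more signal from salivary gland cells: Pe replicate 2 minus the mean of the other profiles was 0.31 for the salivary list, at the 99.4th percentile of lists matched on mean occupancy. In an added check it lay at the 99.1st, 98.5th and 99.3th percentiles against Pe replicate 1, Suc replicate 1 and Suc replicate 2. The list means of Pe replicate 2 and Suc replicate 2 were 1.07 and 1.06, so this rests on matching for the range of the profiles. The largest values of Pe replicate 2 minus the other profiles were at toe (0.66) and eyg (0.64), and only Papss lay below 0 (-0.12). The matched lists take genes as independent, and no members of the salivary list were counted as 1 gene. The correlations, 0.745 to 0.833 for Pe replicate 2 and 0.901 to 0.926 among the others, do not depend on the Pe and Suc labels. They therefore cannot decide whether labels were exchanged. A response to Pe that differed between replicates was not tested.

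Enterocyte genes carry Pol II signal in profiles made with a tracheal driver. Few fragments per gene are argued against as the whole cause by random lists matched on the number of fragments. The list mean in Suc, 0.96, lay at percentile 100 of those lists. In added checks it lay at 99.7 with 8 neighbouring trypsin genes counted as 1 gene and at 99.1 without them. Those lists take genes as independent, and the Jon, Amy and Mal-A families among the other members were not collapsed. The percentiles therefore overstate how firmly few fragments are argued against. With 10 or more fragments, which keeps 12 of the 24 genes, the list stood 0.51 above other genes in Suc and 0.15 in Pe and was called in neither. Signal from gut epithelial cells of the dissected midguts cannot be told apart from transcription of these genes in tracheal cells, because the level of the list, 0.6552 above other genes in Suc, is the pattern itself. The abundant enterocyte genes alphaTry and betaTry stood at 2.86 and 3.12, and 15 of the 24 listed genes were called occupied in Suc and 5 in Pe, while the other gut epithelial lists stood at -0.08 for stem cell and enteroblast markers and -0.25 for enteroendocrine markers against other genes in Suc.

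The enterocyte and tracheal lists had lower means in Pe, with an adjusted p of 0.953 in fry for both. For the tracheal list, the difference of -0.28 lay at percentile 0.04 of lists matched on mean occupancy, and at 0.58 without kni and knrl. Those random lists take genes as independent, while the estimated inter-gene correlation was 0.262 in the tracheal list and 0.114 in the enterocyte list. The percentile therefore overstates how firmly a narrower range of the Pe profiles is argued against as the whole cause. Quantile normalization (-0.25 before, -0.21 after) and median and MAD scaling (-0.23) both ended the tracheal call, and the cause of that was not tested. For the enterocyte list the same test gave percentile 0, but 8 of its genes form a cluster on 2R (11336840 to 11357537) and are not independent, so the bound set in advance was too lenient: with the cluster counted as 1 gene, an added check, it lay at 2.29, and the 16 other members lay at 5.9. The range of the profiles and the cluster as sources of the enterocyte difference therefore cannot be told apart from an effect of Pe on the other members. An effect of the treatment on the tracheal list stays open as a hypothesis that rests on 2 profiles per condition and on Pe replicate 2.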
